A study of Mus musculus with 8 samples.

How the data were processed

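The values are ATAC-seq counts per peak. The deposited table gives whole-number counts for 8 libraries in 122973 peaks of 250 bp, and the authors made it from their reads with Trim Galore, Bowtie2, SAMtools, Picard, MACS3 and deepTools on mm10, per the submitters' processing notes. The versions, the way fragments were counted and any shift for the transposase are not given in the sources used here. The deposited peak list holds the same 122973 positions as the table and no peak scores. Columns that name only age and replicate were taken as the fresh libraries, because the other columns name the culture.

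Each library came from 30000 sorted CD150+ CD48- LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive). Young cells were pooled from 12 mice of 14 weeks and old cells from 2 mice of 25 and 28 months, so age and pool size differ together. Cultured cells were held for 26 hours with stem cell factor at 1 ng/mL, thrombopoietin at 100 ng/mL and 4% bovine serum albumin at 1% oxygen. Total counts in peaks were 2359375 and 1909655 for young fresh, 2630893 and 2737827 for young cultured, 1965126 and 2012622 for old fresh, and 1669317 and 1786605 for old cultured libraries. Intervals and floors cover counting error only.

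Peaks with low counts were removed with filterByExpr of edgeR, which left 77537 and removed 45436. Counts were scaled with TMM factors and fitted with the robust quasi-likelihood model of edgeR with 1 term per group over all 8 libraries, leaving 4 residual degrees of freedom. The 5 comparisons were age in fresh HSCs, age in cultured HSCs, culture in young HSCs, culture in old HSCs, and the interaction of age and culture. Peaks were called at a Benjamini-Hochberg adjusted p under 0.05, and SE is the absolute log2 fold change over the square root of F. Because the young pairs differed by less than sampling noise, each was also summed to 1 sample and the 6 samples fitted again, with 2 residual degrees of freedom. The common dispersion was 0.000991 over 8 libraries and 0.00487 over 6 samples. The methods were tested on simulated data with 8 independent libraries and a dispersion of 0.005, where 0 to 1 of the called peaks per comparison were false. The simulation did not copy young pairs that differ by less than sampling noise. It therefore does not give the number of false calls in these data.

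Peaks were linked to the protein-coding gene that holds them, or else to the nearest within 100 kb, in a GRCm38.p6 gene table, which is the primary assembly of mm10. The table gives no strand, so start sites could not be told from gene ends: a gene boundary peak has its centre within 1 kb of either end of a gene. Of all peaks 86.1% were linked and 16.7% were gene boundary peaks, against 4.35% after every peak was moved by 50 kb. For the 15 gene lists (aged HSC signature, HSC identity, immediate early genes, cytokine signalling feedback, cell cycle, MYC and ribosome biogenesis, hypoxia, p53 targets, NF-kB inflammatory genes, interferon response, and markers of megakaryocytes and platelets, erythroid cells, granulocytes and monocytes, lymphoid cells, and endothelial and stromal cells), 352 of 354 entries matched; Mx1 and Mx2 did not. Lists were tested with camera of limma (preset correlation 0.01, and estimated) and fry on log2 CPM with a prior count of 2, adjusted over 75 tests. The location of changed peaks was compared with Fisher's exact test, two-sided. That test takes peaks as independent, which they are not, so its p-values do not measure a spread between samples. Peaks were not matched on abundance.

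The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes peaks past the threshold whose 2 groups do not overlap, with a mean of at least 1 CPM: the 3 rising and 3 falling peaks with the largest change, 1 per gene; for each list the 2 rising and 2 falling peaks with the lowest p, 1 per gene; and the gene boundary peak and the lowest-p peak of Pbx1. Other Pbx1 peaks, genes listed by called peak, and the second Jun and Fosb positions were chosen after their values were seen.

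The alternatives were DESeq2 size factors, library size only, a loess trend on abundance (span 0.3), the DESeq2 Wald test, no filter, a stricter filter at the median abundance, only the 2 groups compared, a replicate block, each library left out in turn, other rules for linking peaks, and a boundary of 5 kb. Summed young pairs, thinning to the smallest library, linking by nearest boundary, and the peaks above the median abundance for the culture correlation were added after the data were seen. Motifs and corrections for GC content were not analysed here, since a genome sequence and peak scores were not used here, and a stricter peak score was not run. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.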

Results

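Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in mouse hematopoietic stem cells (HSCs) sorted as CD150+ CD48- cells of the lineage-negative, Sca-1-positive, c-Kit-positive bone marrow fraction. Young cells came from pools of 12 mice aged 14 weeks, and old cells from pools of 2 mice aged 25 and 28 months. Each age was taken fresh or after 26 hours of culture with stem cell factor and thrombopoietin at 1% oxygen, which gave 4 groups of 2 libraries. The libraries held between 1669317 and 2737827 counts in 122973 peaks of 250 bp (mm10), and 77537 peaks were tested. At the median tested peak a library held 16 counts. In data simulated from these libraries with 100 peaks changed at each fold and a dispersion of 0.005, 1.5-fold changes were recovered in at most 4% of peaks. There 2-fold changes were recovered in 16% of peaks for age in fresh and 20% for age in cultured cells. For culture they were recovered in 19% in young and 14% in old cells. With so few changed peaks the adjusted threshold is strict, so these shares do not give the recovery where many peaks changed, as with culture. The smallest called changes in these 4 comparisons had an absolute log2 of 0.39, 0.33, 0.27 and 0.32.

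Levels are given in CPM, normalised counts scaled to equal library totals. Where a group holds 3 counts or fewer, a floor or a 95% counting interval is given, and both cover counting error only. A fold given as at least is the level of the higher group over the floor, so it leaves out the counting error of the higher group. The young fresh libraries differed from each other by less than the sampling noise, with a chi-square per degree of freedom of 0.965, and the same held for the young cultured libraries at 0.970. The old pairs, too, differed by less than sampling noise in peaks with over 150 counts per pair, at 0.8375 fresh and 0.9245 cultured. Over all peaks the old pairs differed by more, at 1.14 fresh and 1.10 cultured. Each young pair was therefore counted as 1 sample in the means below and given without an SD, old groups are given as mean ± SD (n = 2), and the totals of changed peaks and the counts in gene lists are also given with the young pairs summed, which leaves 6 samples. In that fit the spread comes from the old pairs alone, with 2 residual degrees of freedom, and culture in young HSCs sets 1 sample against 1, so it does not measure the spread between young samples. The labels do not say whether libraries of 1 group came from separate mice, so p-values measure only the spread between these samples, which may be technical. The first principal component, with 47.4% of the variance, separated fresh from cultured libraries, and the second, with 19.2%, separated young from old. The replicate 1 old libraries lay farther from the young ones (PC2 scores of -92.8 fresh and -68.6 cultured) than replicate 2 (-35.7 and -22.2), and old fresh replicate 2 correlated with young fresh replicate 1 (r = 0.870) as with old fresh replicate 1 (0.867).

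**Figure D1:**
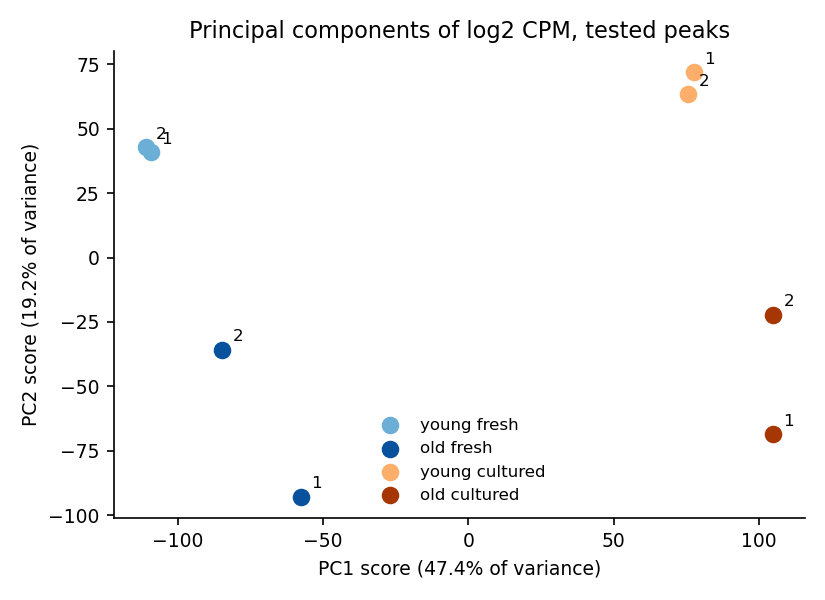
Scores of the 8 libraries on the first 2 principal components of log2 CPM over the 77537 tested peaks, coloured by group and numbered by replicate. Fresh libraries lie at negative and cultured libraries at positive PC1 scores (47.4% of the variance), and young libraries lie above old ones on PC2 (19.2%).

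Pbx1, a homeobox transcription factor gene named in the title of the study, was examined first in every comparison. The gene lies at chromosome 1, 168119364 to 168432365, and 25 tested peaks were linked to it. The peak at its gene boundary, 168432323 to 168432572, measured 76.8 CPM in young fresh, 70.9 ± 3.3 in old fresh, 78.1 in young cultured and 67.5 ± 3.7 CPM in old cultured HSCs, and did not pass the test in any of the 5 comparisons. Inside the gene, the peak at 168225681 to 168225930 fell with age in fresh HSCs from 35.4 to 15.5 ± 1.3 CPM (log2 fold change -1.20, SE 0.22, adjusted p = 0.000276 by edgeR with Benjamini-Hochberg adjustment). The peak at 168362431 to 168362680, also inside the gene, rose with age in fresh HSCs from 17.1 to 30.0 ± 0.6 CPM (log2 0.83, SE 0.23), with an adjusted p of 0.0351 over 8 libraries and 0.0976 with the young pairs summed. By the DESeq2 Wald test 0 of the 25 peaks passed with age in fresh HSCs, with 2 at an unadjusted p under 0.05 against 3 by edgeR, so both calls rest on edgeR. The rising peak (adjusted p = 0.509) and the falling peak (0.0773) lost the call without young fresh replicate 1. The rising peak (adjusted p = 0.0813) lost the call without young fresh replicate 2. The rising peak (adjusted p = 0.265) lost the call without old fresh replicate 1. The rising peak (adjusted p = 0.0860) lost the call without old fresh replicate 2. In cultured HSCs 0 Pbx1-linked peaks passed the age test by edgeR or by DESeq2, with 4 and 1 at an unadjusted p under 0.05, and the lowest adjusted p was 0.0954, at the same peak (log2 0.83, SE 0.27). Culture changed 22.8% of all tested peaks in young and 12.0% in old HSCs, and excess over these shares was not tested for Pbx1. With culture 5 Pbx1-linked peaks changed in young HSCs, 2 rising and 3 falling, and 2 in old HSCs, 1 in each direction. Over 6 samples, with the spread of the old pairs alone, 1 of each stayed under the threshold: the rising peak at 168417130 in young (adjusted p = 0.0458) and the rising peak at 168271263 in old HSCs (0.0388), while the others lay between 0.0690 and 0.120. The first was lost without young fresh replicate 1 (adjusted p = 0.506) and young cultured replicate 2 (0.137), and the second without old fresh replicate 1 (0.133), old fresh replicate 2 (0.0769) and old cultured replicate 2 (0.341). Adjusted over the 25 linked peaks alone, 2 rose and 3 fell in young HSCs, and in old HSCs 0 passed by edgeR, which ends both old calls. By the DESeq2 Wald test 0 of the 25 passed in young or old HSCs, with 0 and 2 at an unadjusted p under 0.05 against 10 and 6 by edgeR.

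**Figure D2:**
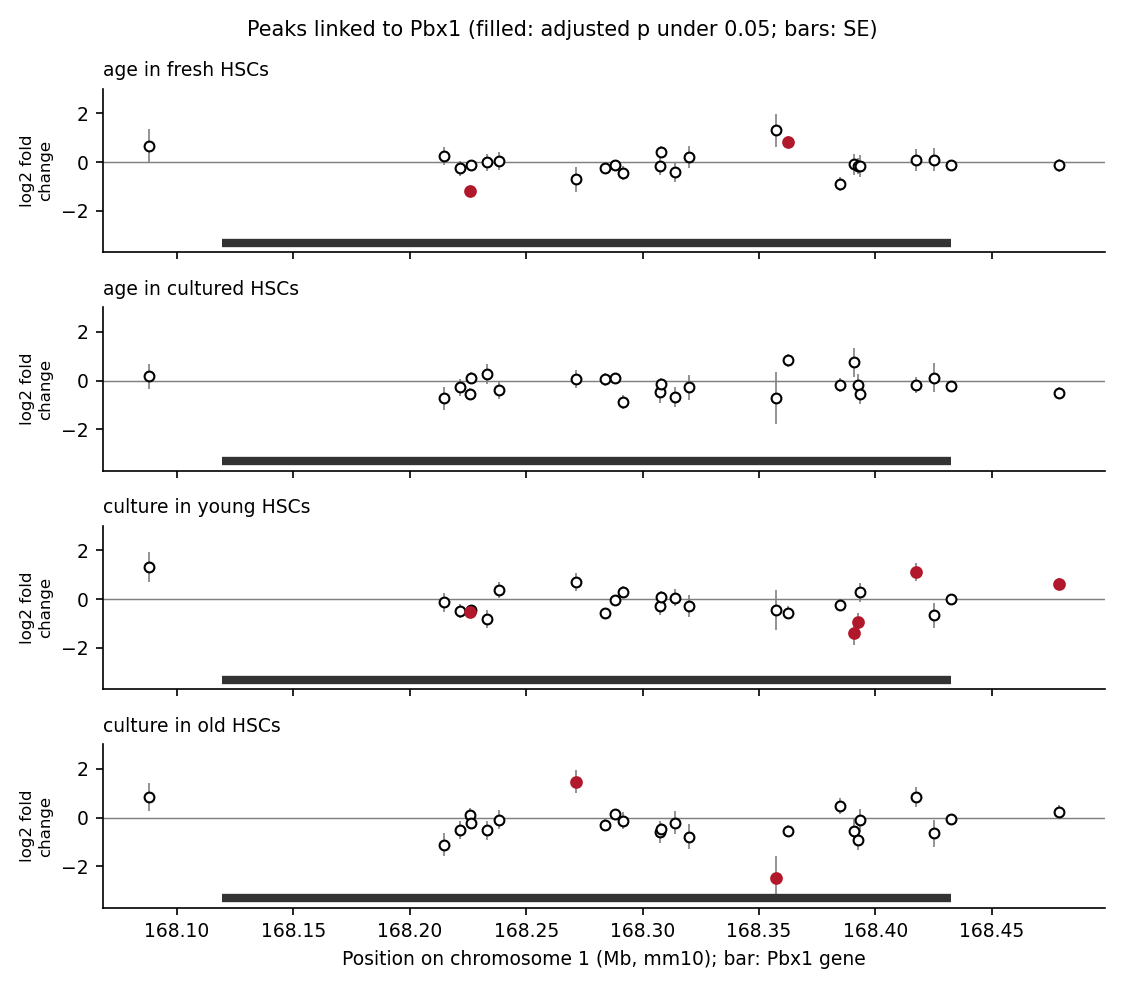
Log2 fold change with its standard error (vertical axis) against position on chromosome 1 in Mb (horizontal axis) for the 25 peaks linked to Pbx1, in the 4 pairwise comparisons; filled points passed an adjusted p of 0.05 and the bar marks the gene. The gene boundary peak near the right end of the bar stays open in every panel, with log2 fold changes of -0.11 and -0.21 with age and 0.03 and -0.07 in culture.

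In fresh HSCs, old cells were more accessible than young cells at aged-HSC genes such as Selp (P-selectin), Cavin2, Enpp5 and Nupr1, and less accessible at Nr4a1, Socs3 and Klf6, which respond quickly to stimulation. At Nr4a1 (chromosome 15, 101275736 to 101275985, 1065 bp outside the gene) the level was 14.0 CPM in young and 1.65 ± 1.5 in old HSCs (log2 -3.02, SE 0.55, adjusted p = 0.000272, edgeR). At the gene boundary of Socs3, a feedback inhibitor of cytokine signalling, it was 20.4 CPM in young and 5.53 ± 1.5 in old HSCs (log2 -1.85, SE 0.35). At that of Klf6, a zinc-finger transcription factor gene, it was 43.1 and 16.6 ± 2.8 CPM (log2 -1.38, SE 0.21). Nr4a1 (adjusted p = 0.0549) lost the call without young fresh replicate 1. Socs3 (adjusted p = 0.0776) lost the call without old fresh replicate 1. In all, 1045 peaks rose and 510 fell with age (edgeR, adjusted p under 0.05), and 771 rose and 213 fell with the young pairs summed, with 982 peaks called in both.

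Of the 220 peaks linked to the aged HSC signature, genes widely reported as higher in aged mouse HSCs, 9 rose and 0 fell with age in fresh cells. Adjusted over the list alone, 19 rose and 2 fell, with the young pairs summed 8 rose, and at an unadjusted p under 0.05 the whole comparison held 10511 of 77537 peaks. The 9 peaks belonged to Cavin2, Clca3a1, Enpp5, Nupr1, Ptprk and Selp. At Cavin2, which encodes a caveolar coat protein, the gene boundary peak went from 42.0 to 72.7 ± 8.5 CPM (log2 0.79, SE 0.13). A peak inside Enpp5 went from 1.17 to 10.8 ± 0.6 CPM (adjusted p = 0.00035), and one inside Selp from 1.11 to 8.05 ± 1.3 CPM (log2 2.88, SE 0.60). Selp (adjusted p = 0.203) lost the call without young fresh replicate 1. Enpp5 (adjusted p = 0.0549) lost the call without young fresh replicate 2. Cavin2 (adjusted p = 0.0573) and Selp (0.0938) lost the call without old fresh replicate 1. The list was higher than other peaks by camera with a preset correlation (adjusted p = 0.0178), and adjusted p = 0.506 with an estimated correlation. For this list adjusted p was 0.0696 without young fresh replicate 1 and 0.127 without old fresh replicate 1. Of the 220 peaks 0 passed the DESeq2 Wald test, with 23 at an unadjusted p under 0.05 against 52 by edgeR.

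Immediate early genes moved in both directions with age in fresh HSCs, with 5 of 182 linked peaks rising and 9 falling. Adjusted over the list alone, 5 rose and 11 fell, and with the young pairs summed 4 rose and 5 fell. A peak inside Jun (chromosome 4, 95049999 to 95050248) rose from 22.5 to 44.7 ± 9.1 CPM (log2 1.00, SE 0.20), and one inside Fosb (chromosome 7, 19308670 to 19308919) rose from 8.45 to 29.5 ± 8.4 CPM (log2 1.77, SE 0.27), while Nr4a1 and Klf6 fell. Of 182 peaks linked to cytokine feedback genes, 1 rose, at Dusp6, and 5 fell, at Ccnd2, Dusp4, Id1, Socs3 and Spry1; adjusted over the list alone, 1 rose and 6 fell. That list was lower than other peaks by camera with the preset correlation (adjusted p = 0.0164), and adjusted p = 0.506 with an estimated correlation. Without young fresh replicate 1 the adjusted p of the list was 0.0568. Of its peaks 1 fell, at Socs3, with the young pairs summed. By the DESeq2 Wald test 2 immediate early and 0 cytokine feedback peaks passed, with 16 and 9 at an unadjusted p under 0.05 against 41 and 29 by edgeR. Jun (adjusted p = 0.141) and Dusp6 (0.211) lost the call without young fresh replicate 1. Dusp6 (adjusted p = 0.328) lost the call without young fresh replicate 2. Jun (adjusted p = 0.188) and Dusp6 (0.392) lost the call without old fresh replicate 1. Dusp6 (adjusted p = 0.0629) lost the call without old fresh replicate 2. Dusp6 (adjusted p = 0.0532) lost the call without young cultured replicate 1. Dusp6 (adjusted p = 0.0628) lost the call without young cultured replicate 2.

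Among other genes in fresh HSCs, peaks at Nfkbiz and Tnfaip3, both regulators of NF-kB signalling, fell with age. The Nfkbiz peak 1161 bp outside the gene went from 13.2 to 2.77 ± 0.73 CPM (log2 -2.20, SE 0.48), and a second peak inside Nfkbiz rose (log2 1.13, SE 0.31). At Hlf, a transcription factor gene of HSC identity, a peak 29201 bp outside the gene went from 13.1 to 3.32 ± 0.72 CPM (log2 -1.99, SE 0.42). E2f8, Tnfrsf10b and Ccnd2 each had a falling peak, with log2 -2.48, -1.13 and -0.90 and SE of 0.69, 0.33 and 0.23. Ifih1 and Pfkfb3 had 1 rising and 1 falling peak each. With the young pairs summed, adjusted p lay between 0.0518 and 0.130 for the peaks named here at Ccnd2, E2f8, Tnfrsf10b, Ifih1, Pfkfb3 and Dusp6, the rising Nfkbiz peak, and those of Col1a2 and Ccdc34 below. The rising Nfkbiz peak (adjusted p = 0.187), Tnfaip3 (0.0745), Hlf (0.258), E2f8 (0.179), Tnfrsf10b (0.0945), Ccnd2 (0.1499), the rising Ifih1 peak (0.235), the falling Ifih1 peak (0.388), the rising Pfkfb3 peak (0.0591) and the falling Pfkfb3 peak (0.113) lost the call without young fresh replicate 1. The rising Nfkbiz peak (adjusted p = 0.286), the falling Nfkbiz peak (0.2003), Tnfaip3 (0.224), E2f8 (0.201), Tnfrsf10b (0.468), Ccnd2 (0.149), the rising Ifih1 peak (0.248), the falling Ifih1 peak (0.102), the rising Pfkfb3 peak (0.389) and the falling Pfkfb3 peak (0.139) lost the call without young fresh replicate 2. The rising Nfkbiz peak (adjusted p = 0.670), the falling Nfkbiz peak (0.130), Tnfaip3 (0.274), Hlf (0.126), E2f8 (0.136), Tnfrsf10b (0.365), Ccnd2 (0.228), the rising Ifih1 peak (0.253), the falling Ifih1 peak (0.275), the rising Pfkfb3 peak (0.294) and the falling Pfkfb3 peak (0.351) lost the call without old fresh replicate 1. Tnfaip3 (adjusted p = 0.0735), E2f8 (0.188), Tnfrsf10b (0.108), Ccnd2 (0.0531), the rising Ifih1 peak (0.0939), the falling Ifih1 peak (0.123) and the rising Pfkfb3 peak (0.0802) lost the call without old fresh replicate 2. Tnfrsf10b (adjusted p = 0.0693) lost the call without young cultured replicate 1. Tnfrsf10b (adjusted p = 0.0629) lost the call without young cultured replicate 2.

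By list, rising and falling peaks in fresh HSCs numbered 1 and 2 of 277 for HSC identity, 0 and 2 of 163 for cell cycle, 1 and 1 of 150 for hypoxia, 0 and 1 of 85 for p53 targets, 1 and 2 of 129 for NF-kB, 1 and 1 of 66 for interferon, and 1 and 0 of 159 for megakaryocyte and platelet genes. Adjusted over each list alone, with edgeR, they numbered 0 and 2, 0 and 2, 0 and 1, 0 and 0, 1 and 3, 1 and 1, and 1 and 0. Of all tested peaks 2.01% passed in this comparison. In these 7 lists 2 falling HSC identity peaks, 2 falling NF-kB peaks and 1 rising megakaryocyte peak kept the call with the young pairs summed. By DESeq2 0 peaks of these lists passed, with 7, 3, 2, 0, 6, 4 and 4 at an unadjusted p under 0.05 against 31, 24, 14, 7, 25, 9 and 20 by edgeR.

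Among peaks at 0 counts in young fresh cells, the one inside Ntrk3, a neurotrophin receptor gene, was at least 7.13-fold higher in old cells, the one inside Zfp804a at least 5.71-fold and the one inside Ccdc34 at least 4.99-fold, against a floor of 3 counts over the group (0.777 CPM). A peak near Alas1 was at least 4.05-fold lower in old cells, against a floor of 0.832 CPM. A peak 2599 bp outside Tra2b was 29.9-fold lower in old cells (95% counting interval 5.00 to 1218), with 1 count left in the old group. Ntrk3 (adjusted p = 0.0745), Zfp804a (0.178), Ccdc34 (0.287), Alas1 (0.131) and Tra2b (0.213) lost the call without young fresh replicate 1. Zfp804a (adjusted p = 0.104), Ccdc34 (0.187) and Alas1 (0.108) lost the call without young fresh replicate 2. Zfp804a (adjusted p = 0.343), Ccdc34 (0.492), Alas1 (0.239) and Tra2b (0.106) lost the call without old fresh replicate 1. Alas1 (adjusted p = 0.0971) lost the call without old fresh replicate 2.

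Few markers of other marrow cells passed the test with age in fresh HSCs, where 2.01% of all tested peaks passed. At that share few calls would be drawn in lists of this size, so these counts do not show that other cells were absent. Of 82 endothelial and stromal peaks 2 rose, at Stab2 (log2 1.88, SE 0.48) and Col1a2 (log2 1.07, SE 0.29), and adjusted over the list alone the count was also 2, with the young pairs summed 1, and by DESeq2 0, with 2 at an unadjusted p under 0.05 against 8 by edgeR. For 51 erythroid, 47 granulocyte and monocyte and 74 lymphoid peaks the count was 0 by edgeR and by DESeq2, also adjusted over each list alone, with 7, 6 and 13 at an unadjusted p under 0.05 by edgeR and 1, 0 and 1 by DESeq2. The median log2 fold changes were 0.02, -0.21 and -0.10 for these 3 lists. Of 57 MYC and ribosome biogenesis peaks 0 passed by either tool, with 5 and 1 at an unadjusted p under 0.05. Stab2 (adjusted p = 0.453) and Col1a2 (0.216) lost the call without young fresh replicate 1. Col1a2 (adjusted p = 0.229) lost the call without young fresh replicate 2. Stab2 (adjusted p = 0.522) and Col1a2 (0.501) lost the call without old fresh replicate 1.

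Single libraries and the test set how many peaks passed in fresh HSCs and how they split. By the DESeq2 Wald test 91 rose and 6 fell, and leaving out each fresh library in turn lowered the share of falling peaks. The count of 1555 peaks changing with age became 212 without old fresh replicate 1, 290 without young fresh replicate 1, 461 without young fresh replicate 2, 1857 without old fresh replicate 2, and 97 by the DESeq2 Wald test.

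In cultured HSCs the age difference was again mostly a gain. By the DESeq2 Wald test 122 peaks rose and 1 fell. By edgeR the share of falling peaks was lower without old cultured replicate 1 and higher without old cultured replicate 2. Peaks near Nr2f2 (an orphan nuclear receptor gene), inside Pcdh15 (a protocadherin gene) and near Il1rapl1 were far more accessible in old cells, and peaks inside Snx14 and at the gene boundary of Flt3, the receptor tyrosine kinase of lymphoid-primed progenitors, were less accessible. The peak 77518 bp outside Nr2f2 (chromosome 7, 70274304 to 70274553) measured 0.838 CPM in young and 32.1 ± 12.3 in old cultured HSCs (log2 5.12, SE 0.47, adjusted p = 1.04e-11, edgeR); it also measured 1.81 CPM in young and 29.5 ± 13.9 in old fresh HSCs. In all, 1431 peaks rose and 297 fell with age after culture (edgeR, adjusted p under 0.05), and 967 rose and 96 fell with the young pairs summed, with 1062 peaks called in both.

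Named peaks with few counts are given as ratios. The Pcdh15 peak was 71.0-fold higher in old cultured cells (95% counting interval 12.1 to 2866), and the Il1rapl1 peak on the X chromosome 50.5-fold (8.43 to 2056), each with 1 count in the young group. The Snx14 peak was at least 4.65-fold lower in old cells, against a floor of 3 counts over the group (1.00 CPM). A peak inside Xrcc6, which encodes a DNA end-joining protein, was 12.7-fold lower (3.29 to 108), and one inside the chromatin remodeller gene Chd7 14.6-fold lower (2.37 to 600.5). Chd7 (adjusted p = 0.0553) lost the call without young fresh replicate 1. Chd7 (adjusted p = 0.288) lost the call without young cultured replicate 1. Xrcc6 (adjusted p = 0.115) lost the call without young cultured replicate 2. Il1rapl1 (adjusted p = 0.0707), Snx14 (0.118), Xrcc6 (0.0623) and Chd7 (0.362) lost the call without old cultured replicate 1. Snx14 (adjusted p = 0.0576) and Chd7 (0.0612) lost the call without old cultured replicate 2.

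In the aged HSC signature, 3 of 220 peaks rose with age after culture and 1 fell, and adjusted over the list alone 2 rose and 1 fell. Only the Ptprk peak kept the call with the young pairs summed. The rising peaks belonged to Cavin2, Dsg2 and Ptprk, and the falling peak lay at the gene boundary of Selp, 7.39-fold lower in old cells (95% counting interval 2.33 to 37.6). Ptprk, a receptor phosphatase gene, went from 16.5 to 36.2 ± 0.6 CPM (log2 1.12, SE 0.22). Of 277 HSC identity peaks 2 rose, inside Fgd5 (log2 2.39, SE 0.66) and at Ndn (log2 1.40, SE 0.39), and adjusted over the list alone the count was 0 by edgeR, with 27 of the list at an unadjusted p under 0.05, 4 by DESeq2. Dsg2 (adjusted p = 0.299), Selp (0.203), Fgd5 (0.249) and Ndn (0.249) lost the call without young cultured replicate 1. Dsg2 (adjusted p = 0.0885), Selp (0.0685), Fgd5 (0.144) and Ndn (0.134) lost the call without young cultured replicate 2. Dsg2 (adjusted p = 0.388), Selp (0.264), Fgd5 (0.297) and Ndn (0.529) lost the call without old cultured replicate 1. Selp (adjusted p = 0.0696) and Fgd5 (0.112) lost the call without old cultured replicate 2.

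Cytokine feedback and immediate early genes gave few changes with age after culture. A peak at Socs2, a feedback inhibitor gene, went from 40.8 to 25.1 ± 2.2 CPM (log2 -0.70, SE 0.19) and one at Jund from 46.5 to 28.5 ± 11.1 CPM (log2 -0.69, SE 0.18), the single call in each of the cytokine feedback and immediate early lists. Adjusted over the list alone the count was 0 by edgeR for both, with 17 and 25 at an unadjusted p under 0.05, 5 and 2 by DESeq2. The immediate early list did not pass camera with the preset correlation (adjusted p = 0.0517), and passed without old fresh replicate 1 (0.0485) and without old cultured replicate 2 (0.0149). Socs2 (adjusted p = 0.212) and Jund (0.180) lost the call without young cultured replicate 1. Socs2 (adjusted p = 0.0925) and Jund (0.0658) lost the call without young cultured replicate 2. Socs2 (adjusted p = 0.294) and Jund (0.620) lost the call without old cultured replicate 1. Socs2 (adjusted p = 0.0601) lost the call without old cultured replicate 2.

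Inflammatory, hypoxia and p53 target genes changed with age at single peaks after culture. Of 129 NF-kB peaks 2 rose, at Bcl3 (log2 2.66, SE 0.50) and Nfkbiz (log2 1.89, SE 0.50), and 3 fell, at Ccl3, Cd83 and Tnfaip3; adjusted over the list alone the counts were the same, 2 and 3, and with the young pairs summed 2 and 1. An Ifih1 peak fell from 7.79 to 1.34 ± 0.06 CPM (log2 -2.49, SE 0.60), and a peak inside Egln3, a prolyl hydroxylase gene of the hypoxia list, from 51.6 to 32.9 ± 8.5 CPM (log2 -0.64, SE 0.17). Of 85 p53 target peaks 2 rose, at Aen (log2 1.72, SE 0.38) and Ccng1 (log2 0.40, SE 0.11), 0 fell, and the list as a whole was lower than other peaks by camera with the preset correlation (adjusted p = 0.0475), with a median log2 fold change of -0.22, and adjusted p = 0.506 with an estimated correlation. Aen encodes a nuclease and Ccng1 a cyclin, and adjusted over the list alone both also rose. The adjusted p of the p53 list was 0.0647 without young fresh replicate 1, 0.112 without young cultured replicate 1, 0.258 without old cultured replicate 1 and 0.0634 without old cultured replicate 2. Rrs1, a ribosome biogenesis gene, rose (log2 0.41, SE 0.12), as did Mmrn1 of the megakaryocyte list (log2 0.57, SE 0.16). Adjusted over each list alone, with edgeR, 1 interferon peak fell, 1 ribosome biogenesis peak rose, 1 megakaryocyte peak rose and 1 fell, and 0 hypoxia peaks passed, with 14 at an unadjusted p under 0.05 and 0 called by DESeq2. The hypoxia list did not pass camera with the preset correlation (adjusted p = 0.0713) and passed without old fresh replicate 1 (0.0485). Nfkbiz (adjusted p = 0.163), Ccl3 (0.153), Cd83 (0.0613), Egln3 (0.296), Ccng1 (0.203), Rrs1 (0.203) and Mmrn1 (0.161) lost the call without young cultured replicate 1. Nfkbiz (adjusted p = 0.15), Ccl3 (0.0515), Cd83 (0.149), Ifih1 (0.195), Egln3 (0.0685), Aen (0.0769), Ccng1 (0.204), Rrs1 (0.184) and Mmrn1 (0.196) lost the call without young cultured replicate 2. Bcl3 (adjusted p = 0.0885), Nfkbiz (0.101), Ccl3 (0.126), Cd83 (0.142), Ifih1 (0.137), Egln3 (0.507), Aen (0.249), Ccng1 (0.407), Rrs1 (0.275) and Mmrn1 (0.297) lost the call without old cultured replicate 1. Nfkbiz (adjusted p = 0.185), Ccl3 (0.0972), Cd83 (0.141), Ifih1 (0.0763), Ccng1 (0.118), Rrs1 (0.191) and Mmrn1 (0.118) lost the call without old cultured replicate 2.

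Among markers of other cells after culture, Stab2 (log2 1.55, SE 0.44) and a peak 72907 bp from Cdh5 (log2 1.45, SE 0.33) rose with age. Prtn3 (log2 -0.69, SE 0.20) and Flt3 (log2 -0.96, SE 0.25) fell, and 0 of 51 erythroid peaks passed by edgeR or DESeq2, with 4 and 0 at an unadjusted p under 0.05. Of 163 cell cycle peaks 0 passed by either tool, with 17 and 3. Marker lists numbered 2 rising of 82 endothelial and stromal peaks, 1 falling of 47 granulocyte and monocyte and 1 falling of 74 lymphoid peaks, with the same counts adjusted over each list alone. Of all tested peaks 2.23% passed in this comparison. Over 6 samples 1 endothelial and stromal peak rose and 1 lymphoid peak fell, and in the lists above 1 p53 target and 1 megakaryocyte peak rose and 1 immediate early and 1 interferon peak fell. The granulocyte and monocyte list did not pass camera with the preset correlation (adjusted p = 0.159) and passed without young cultured replicate 1 (0.0389). Prtn3 (adjusted p = 0.0722) lost the call without young fresh replicate 1. Prtn3 (adjusted p = 0.0710) lost the call without young fresh replicate 2. Stab2 (adjusted p = 0.155), Cdh5 (0.329) and Prtn3 (0.439) lost the call without young cultured replicate 1. Stab2 (adjusted p = 0.260), Prtn3 (0.0541) and Flt3 (0.230) lost the call without young cultured replicate 2. Stab2 (adjusted p = 0.232), Cdh5 (0.134), Prtn3 (0.509) and Flt3 (0.134) lost the call without old cultured replicate 1. Stab2 (adjusted p = 0.161) and Flt3 (0.107) lost the call without old cultured replicate 2. With the young pairs summed, adjusted p lay between 0.0513 and 0.125 for the peaks named above at Chd7, Cavin2, Dsg2, Selp, Fgd5, Ndn, Socs2, Rrs1, Egln3, Ccng1, Ccl3, Tnfaip3, Prtn3 and Stab2. In each of the 15 lists 0 peaks passed by DESeq2 with age in cultured HSCs, with 0 to 9 at an unadjusted p under 0.05 against 4 to 45 by edgeR. The total of 1728 changed peaks became 417 without old cultured replicate 1, 584 without young cultured replicate 1, 836 without young cultured replicate 2, 1829 without old cultured replicate 2, and 123 by the DESeq2 Wald test.

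The age differences in fresh and in cultured HSCs, which share no library, went the same way at many peaks. The labels give the same pool make-up for both states, so fresh and cultured libraries of 1 age may come from the same mice. A difference between pools would then appear in both, and the 2 age effects are not shown to be independent. Without old fresh replicate 1 their correlation across peaks was 0.307. Of the peaks that rose with age, 513 were called in both states, where independent lists would share 19.3, and 24 falling peaks were shared where 1.95 would be. Across all tested peaks, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.452 and Spearman rho = 0.333. Peaks that rose with age were seldom at gene boundaries: 5.45% of those in fresh and 10.2% of those in cultured HSCs were gene boundary peaks, against 23.0% of all tested peaks (odds ratios 0.190 and 0.374, Fisher's exact test, two-sided, adjusted p = 1.92e-54 and 1.89e-36). A further 39.5% and 36.1% of them lay within genes. The Fisher p-values take peaks as independent and do not measure the spread between samples. Of the 297 peaks that fell with age after culture, 40.1% were gene boundary peaks (odds ratio 2.24, adjusted p = 9.18e-11), and of the 510 that fell in fresh HSCs 10.6% (odds ratio 0.394, adjusted p = 6.92e-13), a call lost with a boundary of 5 kb (odds ratio 0.903, adjusted p = 0.2896). The falling calls after culture depended on which old cultured library was kept, and their location was not tested without either. Old cultured replicate 1 held 28.3% of its counts in gene boundary peaks, the other cultured libraries 30.5% to 32.2%.

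**Figure D3:**
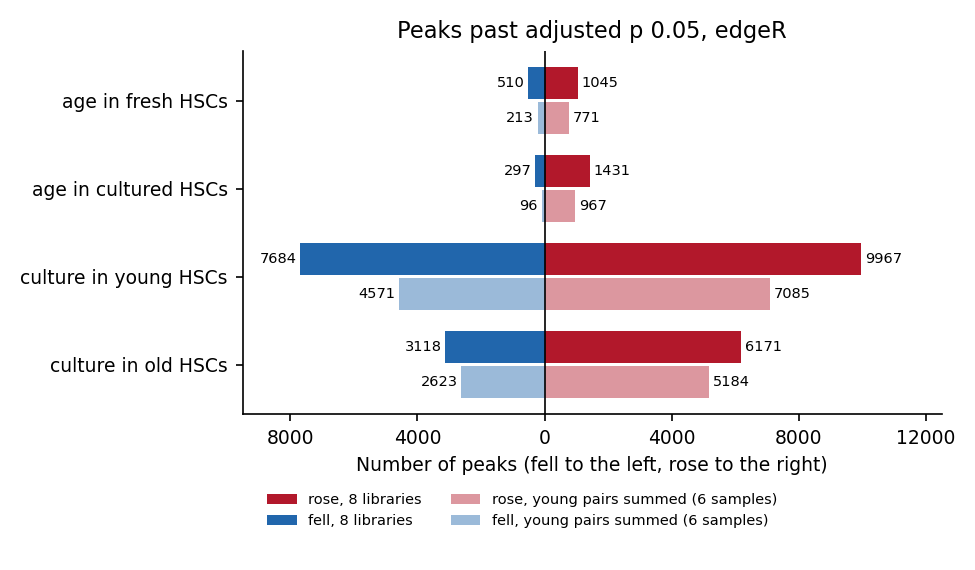
Number of peaks (horizontal axis) that rose, to the right, or fell, to the left, at an adjusted p under 0.05 by edgeR in the 4 pairwise comparisons, over 8 libraries (dark bars) and with the young pairs summed to 6 samples (light bars). In each comparison more peaks rose than fell, from 1045 against 510 with age in fresh HSCs to 9967 against 7684 with culture of young HSCs.

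After 26 hours of culture, young HSCs were less accessible than fresh ones at peaks of the immediate early genes Jun, Fos, Fosb and Nr4a1, which encode transcription factors induced within minutes of stimulation, and more accessible at peaks near Alcam, an adhesion molecule gene, Egln3, Bax and Erg. The gene boundary peak of Jun (chromosome 4, 95049186 to 95049435) measured 61.8 CPM in fresh and 1.25 CPM in cultured young HSCs (log2 -5.51, SE 0.32, adjusted p = 3.44e-22, edgeR). A gene boundary may be the start or the end of a gene, so this loss is not shown to lie at a start site. The Alcam peak, 17369 bp outside the gene (chromosome 16, 52470326 to 52470575), measured 5.83 and 52.4 CPM (log2 3.18, SE 0.24). In all, 9967 peaks rose and 7684 fell (edgeR, adjusted p under 0.05), and 7085 and 4571 with the young pairs summed, where 1 fresh is set against 1 cultured sample and the spread is that of the old pairs, so neither count takes in a spread between separate young samples.

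Of 182 immediate early gene peaks, 54 fell and 24 rose in young HSCs, and adjusted over the list alone 57 fell and 28 rose. Over 6 samples, with the spread of the old pairs alone, 41 fell and 19 rose, and over 8 libraries 26 passed by DESeq2. A peak inside Fosb (19303883 to 19304132) fell from 36.2 to 2.75 CPM (log2 -3.67, SE 0.32), while 2 of the 13 Fosb-linked peaks rose, at 19308670 (log2 1.59, SE 0.27) and 19316602 (log2 0.51, SE 0.15). The Nr4a1 peak named above was 66.0-fold lower (95% counting interval 11.3 to 2654, 1 count in the cultured group), and a peak 37236 bp from Fos was at least 10.6-fold lower against a floor of 0.636 CPM. Klf6 and Ier3 had rising peaks farther from the gene, at 24011 bp (log2 3.25, SE 0.36) and 8161 bp (log2 1.43, SE 0.24). The list as a whole did not pass camera with the preset correlation (adjusted p = 0.0713), and passed without young cultured replicate 1 (adjusted p = 0.0389) and without old fresh replicate 1 (0.0485).

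Cytokine feedback genes, targets and inhibitors of JAK-STAT and MAPK signalling, had 38 falling and 16 rising peaks of 182 in young HSCs, 41 and 20 adjusted over the list alone, 26 and 11 with the young pairs summed, with the same limit, and 9 passed by DESeq2 over 8 libraries. Socs3 fell from 20.4 to 2.70 CPM (log2 -2.85, SE 0.38) and a peak inside Il2ra from 35.0 to 10.2 CPM (log2 -1.76, SE 0.23). A peak 4349 bp from Id1 rose from 21.9 to 51.2 CPM (log2 1.23, SE 0.17), and a peak 27668 bp from Bcl6 was 21.7-fold higher (95% counting interval 5.72 to 184). The list was lower than other peaks by camera with the preset correlation (adjusted p = 0.0475), and adjusted p = 0.506 with an estimated correlation. For these genes adjusted p was 0.0836 without young fresh replicate 1, 0.0573 without young fresh replicate 2, 0.0601 without young cultured replicate 2, 0.0589 without old cultured replicate 1 and 0.0580 without old cultured replicate 2.

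Other groups held rising and falling peaks in culture of young HSCs, where 22.8% of all tested peaks changed. Whether a group exceeded that share was not tested. HSC identity genes had 25 rising and 20 falling peaks of 277, and Erg had both, at 7.35 against 31.6 CPM (log2 2.06, SE 0.26) and at 26.2 against 10.8 CPM (log2 -1.28, SE 0.24). The aged HSC signature had 41 rising and 11 falling of 220, with Ptprk at log2 1.54 (SE 0.18) and the gene boundary peak of Clu at -1.05 (SE 0.22). That list did not pass camera with the preset correlation (adjusted p = 0.0688) and passed without young cultured replicate 1 (0.0412) and without old fresh replicate 1 (0.0485). Cell cycle genes had 18 and 21 of 163, with Cdk6 (log2 1.97, SE 0.27) rising and Ccne1 (log2 -0.97, SE 0.19) falling. Hypoxia genes had 13 and 15 of 150. Egln3 went from 12.0 to 51.6 CPM (log2 2.11, SE 0.21) and a peak inside Mxi1 from 24.7 to 5.08 CPM (log2 -2.26, SE 0.29). Of 85 p53 target peaks 12 rose and 6 fell. The gene boundary peak of Bax, a pro-apoptotic gene, went from 28.7 to 64.3 CPM (log2 1.15, SE 0.14) and a peak inside Tnfrsf10b, a death receptor gene, from 16.2 to 2.11 CPM (log2 -2.86, SE 0.41). NF-kB genes had 18 rising and 19 falling peaks of 129, interferon genes 4 and 9 of 66, and MYC and ribosome biogenesis genes 4 and 8 of 57. Adjusted over each list alone, rising and falling peaks numbered 24 and 20 for HSC identity, 41 and 11 for the aged HSC signature, 18 and 21 for cell cycle, 13 and 15 for hypoxia, 12 and 6 for p53 targets, 19 and 23 for NF-kB, 4 and 9 for interferon and 4 and 8 for MYC genes. These numbers became, with the young pairs summed, 16 and 12 for HSC identity, 32 and 7 for the aged HSC signature, 12 and 12 for cell cycle, 10 and 9 for hypoxia, 10 and 3 for p53 targets, 15 and 7 for NF-kB, 3 and 7 for interferon and 3 and 5 for MYC genes. By DESeq2 8, 12, 5, 4, 7, 3, 1 and 0 peaks of these lists passed, with 8 MYC peaks at an unadjusted p under 0.05 against 22 by edgeR.

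Lineage markers also had changed peaks in young HSCs, where 22.8% of all tested peaks changed, and excess over that share was not tested. Megakaryocyte and platelet genes had 18 rising and 12 falling peaks of 159, erythroid genes 10 and 7 of 51, granulocyte and monocyte genes 5 and 5 of 47, lymphoid genes 8 and 6 of 74, and endothelial and stromal genes 12 and 8 of 82. Adjusted over each list alone these were 18 and 11, 10 and 8, 5 and 3, 7 and 4, and 12 and 8. Over 6 samples they were 13 and 9, 6 and 1, 4 and 2, 4 and 3, and 8 and 5. DESeq2 called 5, 1, 1, 2 and 3 peaks of these lists. A peak inside Ebf1, a B-cell transcription factor gene, was at least 13.4-fold higher after culture, against a floor of 0.777 CPM, and a peak near Gata3 went from 7.93 to 26.6 CPM (log2 1.73, SE 0.27). Peaks at 0 counts in young fresh cells near Stxbp6 and Gm52512 and inside Actn4 were at least 22.4-fold, 19.6-fold and 14.7-fold higher after culture. The count of 17651 changed peaks became 7964 without young fresh replicate 1, 9992 without young fresh replicate 2, 9704 without young cultured replicate 1, 10730 without young cultured replicate 2, and 2488 by the DESeq2 Wald test.

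**Figure D4:**
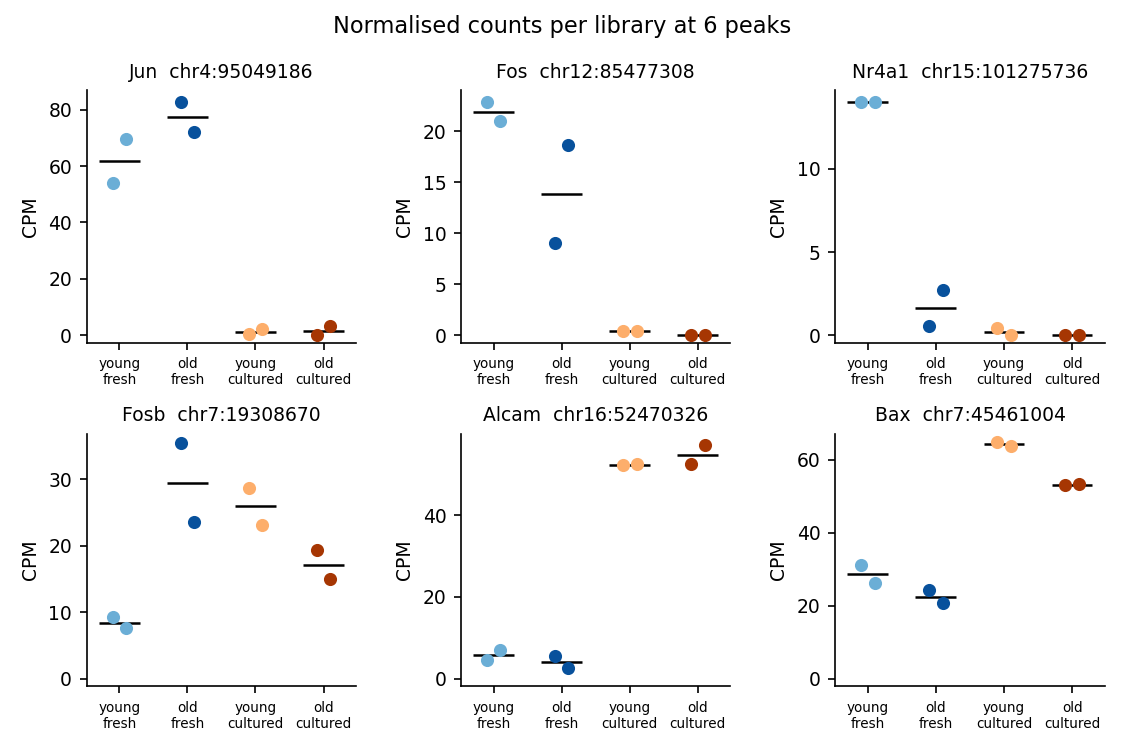
CPM of each library (points) and group mean (lines) at 6 peaks, by group on the horizontal axis; each vertical axis has its own scale. At Jun, Fos and Nr4a1 fresh libraries lie above cultured ones, at Alcam and Bax below, and at Fosb old fresh libraries (mean 29.5 CPM) lie above young fresh ones (mean 8.45 CPM).

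Old HSCs were also less accessible after culture at Jun, Fos and Fosb, together with the heat shock gene Hspa1a, and more accessible at peaks of Alcam, Egln3, Bax and Tek. Jun went from 77.4 ± 7.4 CPM in fresh to 1.62 ± 2.3 in cultured old HSCs (log2 -5.48, SE 0.34, adjusted p = 6.81e-21, edgeR), and Alcam from 4.18 ± 2.0 to 54.8 ± 3.3 CPM (log2 3.70, SE 0.28). The gene boundary peaks of Fos (chromosome 12, 85477308 to 85477557) and Hspa1a held 0 counts after culture and were at least 13.8-fold and 10.2-fold lower, against a floor of 3 counts over the group (1.00 CPM). Here too the start of a gene was not told from its end. In all, 6171 peaks rose and 3118 fell (edgeR, adjusted p under 0.05), and 5184 rose and 2623 fell with the young pairs summed, with 7791 called in both.

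Immediate early genes had 44 falling and 13 rising peaks of 182 in old HSCs, 54 and 21 adjusted over the list alone, and 39 and 10 with the young pairs summed, and 20 passed by DESeq2. The list was lower than other peaks by camera with the preset correlation (adjusted p = 0.0120), and adjusted p = 0.506 with an estimated correlation. Without old cultured replicate 1 the adjusted p of the list was 0.0589. A peak inside Fosb (19307786 to 19308035) went from 26.3 ± 3.8 to 1.99 ± 0.86 CPM (log2 -3.67, SE 0.42), while the distal Klf6 peak rose (log2 2.81, SE 0.36), as did a peak 10782 bp from Jun (log2 2.45, SE 0.48). A peak 53337 bp from Sik1 was at least 6.08-fold lower. Of 66 interferon response peaks 6 fell, at Ifit2, Irf1, Irf7 and Zbp1, and 1 rose, linked to Psmb9, with the same counts adjusted over the list alone and with the young pairs summed. By DESeq2 0 interferon peaks passed, with 7 at an unadjusted p under 0.05 against 19 by edgeR. That list was lower by camera with the preset correlation (adjusted p = 0.0475), and adjusted p = 0.506 with an estimated correlation. For interferon genes adjusted p was 0.0696 without young fresh replicate 1, 0.0573 without young fresh replicate 2, 0.118 without old fresh replicate 2, 0.0734 without old cultured replicate 1 and 0.0696 without old cultured replicate 2. The gene boundary peak of Irf7 went from 10.5 ± 2.1 to 3.67 ± 0.31 CPM (log2 -1.50, SE 0.46). Psmb9 (adjusted p = 0.0947) lost the call without old fresh replicate 1. Sik1 (adjusted p = 0.130), Ifit2 (0.0946), Irf7 (0.171) and Psmb9 (0.0842) lost the call without old fresh replicate 2. Irf7 (adjusted p = 0.106) lost the call without old cultured replicate 1. Ifit2 (adjusted p = 0.138), Irf7 (0.0945) and Psmb9 (0.501) lost the call without old cultured replicate 2.

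With culture of old HSCs 12.0% of all tested peaks changed, and excess of a group over that share was not tested. In the other groups, HSC identity genes had 19 rising and 15 falling peaks of 277, with Tek, the angiopoietin receptor gene, going from 2.77 ± 0.06 to 16.7 ± 1.2 CPM (log2 2.56, SE 0.42) and Prdm16 from 32.7 ± 0.6 to 16.8 ± 1.7 CPM (log2 -0.96, SE 0.23). Prdm16 (adjusted p = 0.0501) lost the call without old cultured replicate 2. The HSC identity list did not pass camera with the preset correlation (adjusted p = 0.169) and passed without old fresh replicate 1 (0.0485). The aged HSC signature had 23 and 7 of 220, with the metallothionein gene Mt2 rising (log2 1.70, SE 0.29). Cytokine feedback genes had 10 and 14 of 182, with Dusp4 (log2 1.21, SE 0.18) rising and Il2ra (log2 -1.09, SE 0.27) falling. Cell cycle genes had 13 and 6 of 163, where a peak inside Cdk6 rose (log2 1.58, SE 0.21) and the gene boundary peak of Ccnd1 fell from 17.7 ± 2.0 to 5.06 ± 1.6 CPM (log2 -1.81, SE 0.37). Hypoxia genes had 11 and 7 of 150, with Egln3 rising (log2 2.19, SE 0.28) and Ldha falling (log2 -1.05, SE 0.21). The hypoxia list did not pass camera either (adjusted p = 0.115) and passed without old fresh replicate 1 (0.0485). Of 85 p53 target peaks 7 rose, Bax (log2 1.24, SE 0.18) and Bbc3 (log2 1.84, SE 0.35) among them, and 6 fell. NF-kB genes had 11 and 4 of 129. A peak inside Nfkb1 was 19.3-fold higher (95% counting interval 4.93 to 166). MYC and ribosome biogenesis genes had 2 and 2 of 57. Adjusted over each list alone, rising and falling peaks numbered 20 and 15 for HSC identity, 26 and 8 for the aged HSC signature, 10 and 14 for cytokine feedback, 13 and 6 for cell cycle, 12 and 7 for hypoxia, 12 and 9 for p53 targets, 11 and 4 for NF-kB and 2 and 1 for MYC genes. With the young pairs summed they numbered 15 and 9 for HSC identity, 20 and 5 for the aged HSC signature, 7 and 13 for cytokine feedback, 11 and 6 for cell cycle, 11 and 7 for hypoxia, 7 and 5 for p53 targets, 8 and 4 for NF-kB and 2 and 2 for MYC genes. By DESeq2 4, 5, 4, 3, 4, 3, 1 and 0 peaks of these lists passed, with 4 MYC peaks at an unadjusted p under 0.05 against 13 by edgeR.

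Lineage markers in old HSCs, where 12.0% of all tested peaks changed, followed with 12 rising and 3 falling of 159 megakaryocyte and platelet peaks, 3 and 3 of 51 erythroid, 2 and 2 of 47 granulocyte and monocyte, 2 and 2 of 74 lymphoid, and 4 and 2 of 82 endothelial and stromal peaks. Adjusted over each list alone the counts were the same except for 4 and 1 endothelial and stromal peaks, and with the young pairs summed they were 10 and 2, 3 and 2, 2 and 2, 2 and 2, and 4 and 1. DESeq2 called 1, 0, 0, 2 and 1 peaks of these lists, with 6 erythroid and 4 granulocyte and monocyte peaks at an unadjusted p under 0.05 against 11 and 11 by edgeR. The tetraspanin gene Cd9 rose (log2 1.35, SE 0.24), and Flt3 fell (log2 -1.05, SE 0.25). Flt3 (adjusted p = 0.0728) lost the call without old fresh replicate 2. Peaks at 0 counts in old fresh cells near Idi2 and inside Efl1 and Esrrg were at least 21.7-fold, 19.7-fold and 14.1-fold higher after culture, against a floor of 0.832 CPM. The count of 9289 changed peaks became 4648 without old fresh replicate 2, 5565 without old cultured replicate 1, 4990 without old cultured replicate 2, and 1183 by the DESeq2 Wald test.

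The culture differences in young and in old HSCs, which share no library, correlated across peaks with r = 0.727 and rho = 0.690. Of rising peaks 4321 were called in both ages, where independent lists would share 793, and of falling peaks 1833 against 309; 4 peaks had opposite calls. Peaks that rose in culture lay away from gene boundaries, at 1596 of 9967 peaks in young and 7.31% in old HSCs, against 23.0% of all tested peaks (odds ratios 0.601 and 0.244, Fisher's exact test, two-sided, adjusted p = 7.38e-76 and 2.02e-254). Here too the p-values take peaks as independent, which they are not, and do not measure the spread between samples. Falling peaks were closer to the background, at 21.2% in young (odds ratio 0.886, adjusted p = 3.52e-05) and 22.1% in old HSCs (odds ratio 0.947, adjusted p = 0.216), and with a boundary of 5 kb both odds ratios were above 1, at 1.18 and 1.12.

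Whether the culture difference itself differed between young and old HSCs was tested by the interaction. A single peak passed, inside Fosb (chromosome 7, 19308670 to 19308919), the transcription factor gene that belongs to the immediate early list. It went from 8.45 to 25.9 CPM with culture in young HSCs and from 29.5 ± 8.4 to 17.1 ± 3.1 CPM in old HSCs (interaction log2 -2.37, SE 0.37, adjusted p = 0.000578 by edgeR over 8 libraries and 0.00218 with the young pairs summed). The Fosb peaks at 19303883 and 19307786 fell with culture in both ages. Adjusted over the immediate early list alone, 1 peak rose and 4 fell in the interaction. Of the peaks in each of the other 14 lists 0 passed by edgeR or DESeq2, with 3 to 16 at an unadjusted p under 0.05 by edgeR. The p53 list did not pass camera with the preset correlation (adjusted p = 0.1496) and passed without old fresh replicate 1 (0.0485). At an unadjusted p under 0.05 the interaction held 4500 of 77537 peaks, 5.80%. In simulated data with 100 such peaks and a dispersion of 0.005, 3% of 2-fold interactions were recovered. Most differences of that size would thus be missed at this depth where few peaks differ. The Fosb call was lost without young fresh replicate 1 (adjusted p = 0.0622), without young fresh replicate 2 (0.135) and without old fresh replicate 1 (0.334), where 0 peaks passed by edgeR with 4048, 3815 and 4961 at an unadjusted p under 0.05, and by the DESeq2 Wald test, where 0 passed with 515.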

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

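The tests of abundance bias, depth and background for the excess of rising peaks, of scaling for the immediate early genes, and of separate libraries for the shared direction of age and culture were chosen only after the result was seen.

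The culture effect differed between young and old HSCs at 1 peak inside Fosb, where the interaction log2 was -2.37 (SE 0.37, adjusted p = 0.000578 by edgeR). Its adjusted p was 0.0622 without young fresh replicate 1, 0.135 without young fresh replicate 2 and 0.334 without old fresh replicate 1. The immediate early list also differed in the interaction when changes in either direction were counted (fry, mixed, adjusted p = 0.0434), with a median log2 of -0.0514, but not in a shared direction: adjusted p was 0.496 by camera with the preset correlation, 0.749 with an estimated correlation and 0.708 by fry. By directional fry no list passed in any of the 5 comparisons, and the lowest adjusted p was 0.0925.

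More peaks rose than fell with age, in fresh and in cultured HSCs. The lower share of rising peaks over both comparisons was 67.2% in the main fit. It was 72.3% after thinning to the smallest library, which argues against lower depth of the old libraries. After an abundance trend was removed it was 67.4%, which argues only against a trend common to peaks of like abundance. A bias limited to few peaks would not be removed in that way and stays open. Higher background in the old libraries cannot be told apart: the share was 69.3% with gene boundary peaks left out, but only 57 of 1045 and 146 of 1431 rising peaks lie there, so this test decides nothing, and the old libraries hold more counts outside the tested peaks (11.3% and 10.6% against 10.3% and 10.2% fresh, 12.3% and 12.0% against 11.2% and 11.6% cultured). The share of counts in gene boundary peaks does not separate the ages (31.5% and 33.3% in old against 32.3% and 33.2% in young fresh, 28.3% and 30.8% against 32.2% and 30.5% cultured), so the tables point both ways. The median log2 fold change with age was lowest on chromosomes 19 (-0.115 fresh, -0.164 cultured) and 11 (-0.099 and -0.154). Corrections for GC content were not run, so a bias by sequence content stays open for this excess. Age and pool size differ together and nothing here separates them, and a difference of old HSCs themselves may underlie the excess and was not tested.

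More peaks of immediate early genes fell than rose in culture, 54 against 24 in young and 44 against 13 in old HSCs, but by camera the list did not pass in young HSCs (adjusted p = 0.0713), and in old HSCs it passed with the preset correlation (0.0120) but not with an estimated one (0.506). The median log2 fold change of peaks within 20 kb was at most -0.36 over 4 scalings and both ages. That is below the medians of all tested peaks, which ran from -0.041 to 0.0074. These scalings differed too little to bring it near 0, so the test cannot decide on scaling. A shift of overall accessibility was not tested. At 20 to 100 kb the median was 0.28 in young and 0.17 in old HSCs. Activation of the cells during isolation and its decay in culture cannot be told apart from an effect of culture: the median of heat shock genes, another group induced by isolation, lay at percentile 76.6 of matched random sets in young and 5.15 in old HSCs. Of its 19 peaks 3 fell and 1 rose in young and 4 fell and 0 rose in old HSCs by edgeR. The Hsp90aa1 peak at 110690586 fell, with log2 -5.21 (SE 0.47) in young and -3.69 (SE 0.44) in old HSCs. The other Hsp90aa1 gene boundary peak, at 110696195, did not pass, with log2 0.38 (SE 0.24) and 0.21 (SE 0.28). Hspa1a, at least 10.2-fold lower after culture of old HSCs, was not in the set. A response of the cells to the culture stays open and untested.

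Peaks that rose with age also tended to rise in culture: 72.7% of those in fresh and 75.2% of those in cultured HSCs had a positive average culture effect, against 49.4% of all tested peaks, while peaks that fell with age did not share 1 direction, at 38.6% in fresh and 69.0% in cultured HSCs. Noise in shared libraries cannot be told apart. Effects from separate libraries correlated at 0.0869 and 0.149, but the young pairs differ by less than sampling noise, so noise of a young sample may stay in both effects. Across peaks, which are not independent replicates, the average effects correlated at 0.168 against at most 0.101 in 20 simulated sets, short of the margin of 0.1 set before. Their covariance was 0.0464 against a simulated mean of 0.00583, which goes against noise, but the simulation set a dispersion of 0.005 and 8 independent libraries, so it does not exclude it. An abundance trend stays open too, because the correlation after its removal was 0.121, between the bounds set before, and a shared change with age and culture was not tested apart from it. Chromosome 19 had the lowest median log2 fold change with age and also with culture (-0.181 in young and -0.166 in old HSCs). A bias by sequence content thus stays open here as well, since corrections for GC content were not run.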

How the results depend on the processing

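Summed young pairs, thinning, linking by nearest boundary and the more abundant peaks for the culture correlation were chosen only after the results were seen. For each change the cause was not tested unless it is given.

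The DESeq2 Wald test called 97 peaks with age in fresh HSCs, 123 with age in cultured HSCs, 2488 with culture in young and 1183 with culture in old HSCs, and 0 in the interaction (515 at an unadjusted p under 0.05). DESeq2 set a median dispersion over peaks of 0.0933, and the common dispersion of edgeR was 0.000991, which are unlike measures. The peak-wise estimate of DESeq2 was at or under 1e-06 in 88.8% of peaks. Data for age in fresh HSCs were simulated with 200 changed peaks and a dispersion of 0.005, near the 0.00487 of edgeR with the young pairs summed. There DESeq2 recovered 0.5% of 2-fold changes and edgeR 19.5%. Unchanged peaks had an unadjusted p under 0.05 in 0.46% by DESeq2 and 4.92% by edgeR. DESeq2 was conservative there, so a count of 0 by it says little. Higher dispersions were not simulated. The stricter filter called 887, 884, 10495 and 5791 peaks in the same order, over fewer tested peaks. Summing the young pairs gave 984, 1063 and 11656 peaks in the first 3 comparisons.

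Leaving out each library in turn gave 212 to 1857 peaks for age in fresh HSCs, 417 to 1926 for age in cultured HSCs, 7964 to 18427 for culture in young HSCs, 4648 to 8615 for culture in old HSCs, and 0 to 1 for the interaction. With the replicate number as a block the counts were 1415, 1501, 16788, 8761 and 1. Differences between replicates correlated at -0.0613 to -0.00163 in the 5 pairs of groups with a young group. The young pairs differ by less than sampling noise, so values near 0 would be seen with or without pairing. Whether the numbers pair those groups thus cannot be decided. Old fresh and old cultured libraries gave 0.129, and a replicate effect shared by the old libraries stays open.

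Across peaks, which are not independent replicates, the age effects in fresh and cultured HSCs correlated at 0.307 to 0.444 with a library left out, 0.380 with no filter and 0.401 after thinning. The culture effects correlated at 0.644 to 0.701 with a library left out, 0.585 with no filter, 0.777 with the stricter filter and in the more abundant peaks, and 0.682 after thinning.

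Estimated correlation ended all 6 list calls (adjusted p = 0.506). Linking by gene boundary ended 5, at 0.210 for the aged HSC signature and 0.334 for cytokine feedback with age in fresh HSCs, 0.223 for p53 targets with age in cultured HSCs, 0.294 for cytokine feedback with culture in young and 0.108 for interferon with culture in old HSCs. Immediate early genes in culture of young HSCs passed with gene boundaries (0.00151) and within 20 kb (0.000197). With age in cultured HSCs they passed within 20 kb (0.0434), by nearest boundary (0.0359), with the replicate block (0.0478) and with the young pairs summed (0.0415). Cytokine feedback in culture of old HSCs passed within 20 kb (0.0434).

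With a library left out, adjusted p with age in fresh HSCs lay between 0.0149 and 0.127 for the aged HSC signature and 0.0136 and 0.0568 for cytokine feedback. With age in cultured HSCs it lay between 0.0149 and 0.432 for immediate early genes, 0.0485 and 0.279 for hypoxia, 0.0386 and 0.258 for p53 targets, and 0.0389 and 0.556 for granulocyte and monocyte markers. In culture of young HSCs it lay between 0.0412 and 0.119 for the aged HSC signature, 0.0389 and 0.114 for immediate early genes, and 0.0389 and 0.0836 for cytokine feedback. In culture of old HSCs it lay between 0.0485 and 0.578 for HSC identity, 0.00137 and 0.0589 for immediate early genes, 0.0485 and 0.373 for hypoxia, and 0.0389 and 0.118 for interferon. In the interaction it lay between 0.0485 and 0.604 for p53 targets.

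With a boundary of 5 kb the odds ratio of falling peaks went from 0.394 to 0.903 for age in fresh HSCs, and turned from 0.886 to 1.18 for culture in young and from 0.947 to 1.12 for culture in old HSCs. Corrections for GC content and a stricter peak score were not run, since a genome sequence and peak scores were not used here.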

Other observations

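The choice to count called peaks per gene, and the genes named here, came after the values were seen.

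Peaks that rose with age gathered in some genes. The draw used for this was not matched on location. Gene boundary peaks make up 23.0% of tested peaks and are seldom among the rising ones, so genes with many other peaks pass more easily. More peaks rose than a hypergeometric draw gives (Benjamini-Hochberg over 15942 genes, peaks in 1 gene not being independent) in 20 genes in fresh and 62 genes in cultured HSCs, 17 of them in both. Kcnb2, a potassium channel gene, had 7 of 11 linked peaks rising with age in cultured HSCs where 0.149 would be drawn, Kcnn2 10 of 19, Naaladl2 9 of 16, Nlgn1 9 of 21 and Lrfn5 6 of 8. With the young pairs summed, 6 of these peaks kept the call in Kcnb2, 5 in Kcnn2, 6 in Naaladl2, 5 in Nlgn1 and 5 in Lrfn5. Of these Nlgn1 passed in cultured HSCs only. Epha6, Nrg3, Pcdh9, Lsamp and Rbfox1 passed in both states.

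In culture, falling peaks gathered in Fos and Fosb in both ages. Of 13 peaks linked to each gene, 10 fell in Fos and 10 in Fosb in young HSCs, and 7 in Fos and 10 in Fosb in old HSCs, and 9, 9, 7 and 10 with the young pairs summed, where the old pairs alone give the spread. In young HSCs 2 other Fosb peaks rose. Fhit had 17 of 35 peaks rising in young and 13 in old HSCs, 15 and 10 with the young pairs summed. For immediate early genes the median log2 fold change of peaks within 20 kb was -0.37 in young and -0.47 in old HSCs (126 peaks, 23 genes), and between 20 and 100 kb 0.28 and 0.17 (56 peaks, 11 genes). The difference was not tested, and the gene sets differ.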
